A study of Mus musculus with 2 samples.

How the data were processed

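The series holds 2 RNA-seq libraries of mouse midbrain taken on postnatal day 0 from the B6NCrl strain, a C57BL/6N line of laboratory mice. Each library was made from the RNA of 1 whole midbrain, from pup 1 (replicate 1) and pup 3 (replicate 2). Per the labels' protocols, RNA was extracted with a mirVana kit, RNA longer than the small-RNA class was kept, and 13 pg of total RNA, given as 1 cell-equivalent, went into a SMART-type amplification with synthetic spike-in RNAs. The labels call the assay single-cell RNA-seq, although the material is RNA of a tissue and no cell was isolated. Sex was not recorded, and the labels name 1 donor record for both pups. Both libraries form 1 group, so no condition was compared. With 2 pups a two-sided exact test across pups could not go below p = 0.5, and no such test was run.

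Per the file headers, reads were aligned to mm10 with GENCODE release M4, and gene and transcript tables were made per library. The aligner, the quantification program, their versions and the use of strand in counting are not given in the sources used here. The column names are those that RSEM writes. The deposited expected counts are estimates that divide reads matching several genes, so they need not be whole, and they were rounded for every counting interval. The deposited TPM values are counts divided by effective length and scaled to a common total over all rows of a table, spike-ins and tRNA rows included. The deposited FPKM values and the posterior mean counts and TPM were used in alternatives. The deposited lower and upper bounds of the TPM interval were used for gene pairs. The deposited percent of a gene's abundance on each transcript was used for isoforms. Each gene table had 69691 rows, of which 43346 were mouse genes, 26248 tRNA rows and 97 spike-in rows, including 1 phiX row with 0 counts in either library. Symbols were found for 42462 gene identifiers, and the 884 without one held 0.0904% and 0.139% of gene counts. Coordinates are from GENCODE M21 on GRCm38, the assembly also called mm10.

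A gene counted as detected at a TPM of 1 or more. Correlations were taken across genes on log2(TPM + 1), for genes detected in at least 1 library, and carry no p-value because genes are not replicates. A gene was listed as differing over 4-fold when the whole exact (Clopper-Pearson) 95% interval of the count ratio, scaled by each library's total over genes, lay beyond 4-fold. This compares 2 libraries, not conditions. Where a library had 0 counts, the fold given is the end of the exact 95% interval nearer to 1, a lower bound. For ranking genes, counts under a floor of 3 were taken as 3. Intervals and floors cover counting error only, since reads amplified from few molecules are not independent. For 35 gene lists, the members detected in both, 1 or neither library were counted. A list with at least 5 detected members was given the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean expression in 20 bins. For 10 gene pairs, the log2 ratio of TPM + 1 was taken within each library, and a direction was named only where both pups agreed and the deposited intervals did not overlap in either pup. Isoform agreement used genes with at least 2 transcripts and 50 expected counts in each library.

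The genes named were fixed by rule: the 15 genes with the highest mean TPM outside the mitochondrial genome, up to 4 members per list by mean TPM, list members at 0 in both libraries, both genes of each pair, 5 genes per direction with the largest ratio among those over 4-fold apart at a mean TPM of 20 or more, every sex-linked gene, and isoforms of 8 genes. Lists, pairs, the tests of the report and most alternatives were chosen before the data were examined, while some tests of the closing section were chosen afterwards and are named there. List members without a row under their symbol were Lhfpl3, Hbb-b1, Hbb-b2, Rmst and Peg13, and Ca8 was found under Car8. Some genes that the rule selects are not reported here.

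Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, biopython 1.88 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, which gave only scaling factors. The size rule was tested on simulated counts of 43346 genes: 98% of 100 genes changed 8-fold were listed, and 0% of 100 genes changed 2-fold. None of the 43146 unchanged genes was listed, a share of 0%. Only 14629 of the 43346 genes had a count in either library, and the rest were simulated at 0. The simulation held counting error only, so it does not show how often the rule lists unchanged genes in libraries amplified from few molecules. On simulated normal ratios over 12144 genes, 6% of 100 unchanged lists and 100% of 100 lists shifted 8-fold fell outside the middle 95% of random lists. In the data, this middle range reached a median log2 ratio of 3.65 for oligodendrocyte precursor genes and 3.42 for sex-linked genes. Both lie beyond an 8-fold shift, so the simulated recovery does not hold for every list. Alternatives covered the detection threshold, pseudocount, low-value filters, unit, scaling, fold and interval of the size rule, bins, and each library left out. Raw reads and coverage tracks were not used here.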

Results

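RNA of a newborn mouse midbrain was measured by amplified RNA-seq in 2 libraries of 13 pg of total RNA each, the amount of about 1 cell. The midbrain holds the dopamine neurons of the substantia nigra and the tectum. The libraries came from pup 1 and pup 3, which form a single group. They held 26583225 and 33142647 expected counts, so that 3 counts, the limit that a count of 0 allows, equalled 0.113 and 0.0905 CPM. Levels are TPM as mean ± SD over n = 2 pups unless both libraries are given. With 1 library per pup, differences between pups have no replicate check.

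Tuba1a, an alpha tubulin of growing neurons (ENSMUSG00000072235.5, GRCm38 chromosome 15, 98949837 to 98953703), had the highest mean level in the libraries, 20543 ± 5993. Other genes among the 15 highest were Ubb (6424 ± 1218), which encodes ubiquitin, Stmn1 (5824 ± 659), a regulator of microtubules, and the actins Actb (5303 ± 1573) and Actg1 (4332 ± 455). Ftl1, the light chain of the iron store ferritin, stood at 4910 ± 913, the translation factor Eef1a1 at 4418 ± 2090, the nuclear noncoding RNA Malat1 at 4188 ± 2168 and Tubb2a at 4147 ± 825. Gm28437, Gm28661, Gm10925 and Gm29216 were also in this set. They are pseudogenes of chromosome 1 between 24613189 and 24616197. Their sequences were 98.0% to 100% identical to mt-Co3, mt-Co2, mt-Atp6 and mt-Co1, so reads could match both, and in pup 1 the deposited posterior SD was 50270 of 163855 counts for Gm28437 but 199 of 25337 for Gm29216. Gm42418, a noncoding gene on chromosome 17 at 39846958 to 39848788, read 21358 TPM in pup 1 and 3502 in pup 3. Gm22133 (4707 ± 1141) is a short gene that lies inside Ftl1, and its level is uncertain.

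All 16 pan-neuronal genes were detected in both pups. They were led by Tubb3 (3861 ± 2923), the neuronal beta tubulin, Stmn2 (2311 ± 360), the growth cone protein Gap43 (2308 ± 131) and Uchl1 (1323 ± 774). All 13 synaptic vesicle genes were also read in both, with Rab3a at 764 ± 75.1, Vamp2 at 350.3 ± 77.3 and Nsf at 269 ± 30.4. Of 19 glutamate and GABA receptor subunits, 16 were detected in both pups. Among the highest were Gria2 (184 ± 68.5), Gabrb2 (65.4 ± 8.70) and Gabra3 (64.5 ± 38.0), and Grin2a and Grin2c were listed at 0 in both.

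Of 16 dopaminergic genes, 3 were detected in both pups, 4 in pup 1 only, 1 in pup 3 only and 8 in neither. Th, the rate-limiting enzyme of dopamine synthesis (ENSMUSG00000000214.6, chromosome 7, 142892752 to 142931128), was at 42.7 ± 5.90. Aldh1a1 read 0 in pup 1 and 60.8 in pup 3, Nr4a2 3.08 and 57.0, and the decarboxylase Ddc 6.88 and 38.6, each over 4-fold higher in pup 3. Of the list, 4 members were over 4-fold higher in pup 3 and 6 in pup 1. Among the latter, named after their values were seen, Slc18a2 read 15.7 and 0, Pitx3 8.14 and 0, Lmx1b 3.88 and 0 and Slc6a3 2.38 and 0. Foxa1, Foxa2, Gch1, Drd2 and Kcnj6 were at 0 in both. Of 9 GABAergic genes, 5 were in both, among them Gad1 (116 ± 29.4), which makes GABA, Gata3 (47.8 ± 25.8) and Gad2 (3.24 and 37.8), with Gata2 and Tal2 at 0. Of 8 glutamatergic and tectal genes, 3 were in both. Slc17a6, the vesicular glutamate transporter of subcortical neurons, was at 139 ± 57.8, Pou4f1 at 47.3 ± 15.1 and Slc17a8 at 5.39 and 0, while Slc17a7 and Pou4f2 were at 0. Among 6 cholinergic genes only Isl1 (6.45 and 32.2) was in both; Slc18a3 read 15.1 and 0, and Chat, Slc5a7 and Phox2a were at 0. Among 5 serotonergic and noradrenergic genes, the serotonin transporter Slc6a4 (33.4 ± 14.6) was in both, Tph2 read 0.39 and 0, and Fev, Dbh and Slc6a2 were at 0. Of 14 neuropeptides, 7 were in both, with Sst (357 ± 135), Npy (167 ± 46.3), Tac1 (118 ± 24.9) and Cck (63.0 ± 52.6) highest, and Pdyn, Vip, Crh and Hcrt were at 0.

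All 14 Hox genes of hindbrain and spinal cord had 0 counts in both libraries. Of 14 midbrain patterning factors only Meis2 (31.8 in pup 1 and 102.2 in pup 3) was detected in both, 4 were in pup 1 only and 5 in pup 3 only. The count in both was 5 at a TPM of 0.1, 4 at 10 counts and 2 with posterior mean TPM, and 5 and 6 were detected in pup 1 and pup 3 taken alone. Otx2, a homeobox gene of forebrain and midbrain, read 40.6 and 0.40, Meis1 31.1 and 0.02, and Pax3 15.8 and 0, and Dmbx1 and Irx2 were at 0. Irx3 (0 and 9.03) and Pax7 (0.14 and 6.76), named after their values were seen, were read in pup 3 only at this threshold. Of 14 forebrain factors, 4 were in both pups, among them Neurod6 (37.3 ± 13.0), Six3 (17.3 ± 5.85) and Dlx1 (8.99 ± 2.25), whereas Dlx5 read 0 and 32.4. The cortical factors Emx1, Emx2, Tbr1, Eomes and Fezf2, with Lhx6 and Dlx2, were at 0. Of 9 cerebellar genes, Zic1 (13.5 and 22.3) was in both, Car8 read 0.47 and 13.4 and Zic2 0 and 4.18, and Atoh1, Pcp2, Gabra6, Skor2 and Fat2 were at 0. Of 18 axon guidance genes, 11 were in both, 1 in pup 1 only and 6 in pup 3 only. Their highest members were Efna5 (98.7 and 23.6), Robo2 (51.4 ± 10.3), Nrp1 (33.2 ± 24.1) and Sema3a (0 and 41.0).

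Of 16 radial glial and astrocyte genes, 13 were detected in both pups. Fabp7, a fatty acid binding protein of radial glia, stood at 1719 ± 473, Aldoc at 391 ± 112, Vim at 187 ± 32.1 and the glutamine synthetase Glul at 158 ± 65.8. Gfap, a filament of mature astrocytes, had 0 counts in both. Of 7 oligodendrocyte precursor genes, 4 were in both, with Cspg5 at 32.9 ± 12.2, Pdgfra at 27.8 ± 4.79, Sox10 at 23.4 and 0, and Olig2 at 1.18 and 15.4. Of 8 myelin genes, 2 were in both, among them Mbp, the myelin basic protein (28.6 and 53.0). Cnp read 35.1 and 0 and Cldn11 18.6 and 0, and Mag, Mobp and Mal were at 0. Microglial genes were read in both pups for 6 of 12, including the complement genes C1qc (38.2 ± 4.65) and C1qb (26.2 ± 18.3), and Ctss (55.3 and 1.75), with Tmem119 and Fcrls at 0.

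Of 11 endothelial genes, 3 were in both pups, with the tight junction gene Cldn5 at 131 ± 23.0 and the glucose transporter Slc2a1 at 43.5 ± 30.3. Esam read 49.8 and 0, Ly6c1 0 and 45.3, and Slco1a4 and Tek 0 in both. Of 8 mural cell genes, 3 were in both, led by Vtn (72.2 ± 11.01) and Rgs5 (43.7 ± 27.5), with Acta2 at 0 and 8.61, Kcnj8 at 8.02 and 0, and Anpep and Tagln at 0. All 8 meningeal fibroblast genes were in both, led by the prostaglandin D synthase Ptgds (3034 ± 678), Igf2 (232 ± 37.4), Dcn (81.0 ± 42.3) and Slc6a13 (66.9 ± 15.7). Of 10 erythroid genes, 4 were in both, the adult haemoglobin genes Hba-a2 (916 ± 259), Hbb-bs (647 ± 242), Hba-a1 (445 ± 165) and Hbb-bt (273 ± 152). The deposited counts divide reads within these near-identical globin pairs, while the embryonic Hba-x, Hbb-y and Hbb-bh1 were at 0. Of 9 ependymal and choroid plexus genes none was in both: Rsph1 read 0 and 32.9, Ttr 0.05 and 0.16, Foxj1 0 and 0.02 and Aqp1 0.02 and 0, and Kl, Folr1, Clic6, Kcnj13 and Pifo were at 0. Of 12 genes of other organs, Apoa1 (7.01 and 2.02) was in both, Alb read 0.63 and 0.81 and Krt5 0.03 and 0, and 9 were at 0.

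**Figure D1:**
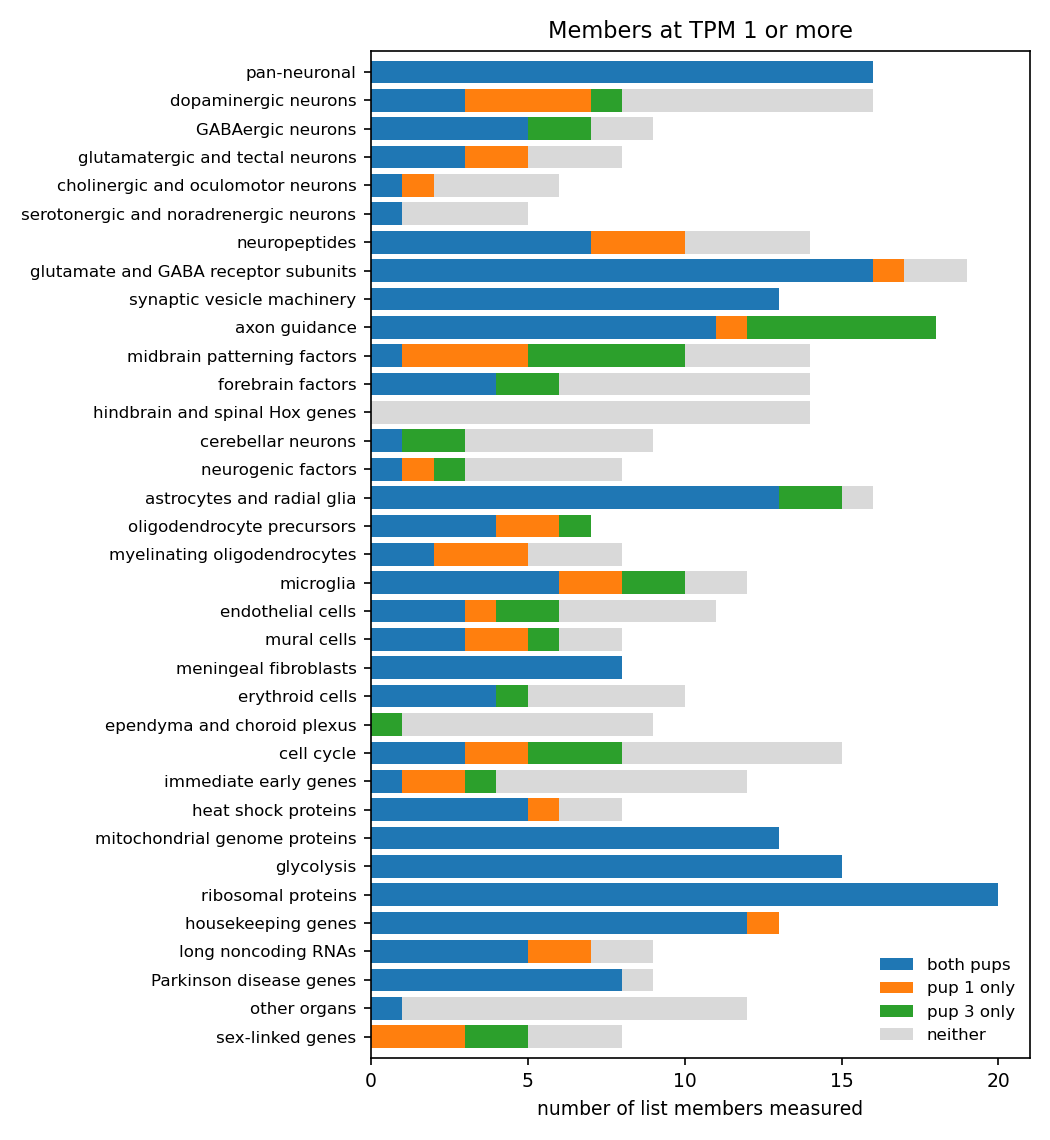
Number of measured members of each of 35 gene lists at TPM 1 or more in both pups, in pup 1 only, in pup 3 only or in neither; bar length is the number of members measured. All 16 pan-neuronal genes were in both pups, and none of 14 Hox genes was in either.

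Of 15 cell cycle genes, 3 were in both. Pcna, the replication clamp, read 24.0 and 122 TPM, Ccnb1 0.06 and 69.1, Cdk1 44.9 and 0.84 and Mcm5 0.24 and 32.1, and Aurkb, Bub1, Mcm2 and Birc5 were at 0. Of 8 neurogenic factors, Notch1 (1.03 and 6.37) was in both, Neurod1 read 0 and 18.2, Dll3 3.07 and 0 and Dll1 0.71 and 0, with Neurog1, Neurog2 and Hes1 at 0. Of 12 immediate early genes, only Jun (2.26 and 2.27) was in both; Dusp1 read 70.6 and 0, Atf3 0 and 13.5 and Npas4 2.78 and 0, and 7 genes, Fos, Egr1 and Arc among them, were at 0. Of 8 heat shock genes, 5 were in both, led by Hspa8 (4268 in pup 1 and 1587 in pup 3), Hsp90ab1 (1740 ± 294), Hsp90aa1 (558 and 1893) and Hspa5 (286 ± 36.1), with Hspa1b and Hspb1 at 0.

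All 13 mitochondrial genome proteins, 15 glycolysis genes and 20 ribosomal proteins were in both pups. Mitochondrial genes included mt-Atp8 (9619 ± 60.0), mt-Atp6 (9294 ± 1098), mt-Cytb (6091 ± 762) and mt-Nd1 (5936 ± 907). Of these, mt-Atp6 shares its sequence with the copy Gm10925, so its level depends on how reads were divided between them. Glycolysis was led by Gapdh (1287 ± 251), Eno1 (1015 ± 218), Aldoa (888 ± 529) and Pkm (729 ± 243), and the ribosomal set included Rplp1 (1204 ± 35.2), Rps18 (1051 ± 462) and Rplp0 (1043 ± 571). Of 13 housekeeping genes, 12 were in both. Of 9 long noncoding RNAs, 5 were in both, among them Meg3 (1464 ± 2.92), Snhg11 (352 ± 58.0) and Rian (347 ± 82.9). Of 9 Parkinson disease genes, 8 were in both, with Park7 at 518 ± 19.5, Vps35 at 166 ± 32.5 and Synj1 at 93.8 ± 4.74, and Lrrk2 was at 0.

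Ratios within each library placed 8 of 10 fixed gene pairs on the same side in both pups. Mean log2 ratios of TPM + 1 were 5.03 ± 0.10 for Grin2b over Grin2a, 7.06 ± 0.62 for Slc17a6 over Slc17a7, 4.13 ± 0.35 for the glutamate transporters Slc1a3 over Slc1a2, and 2.18 ± 0.51 for Dcx, of young neurons, over Rbfox3, of older ones. Fabp7 exceeded Gfap by 10.72 ± 0.40 and Hba-a1 exceeded Hba-x by 8.75 ± 0.55. Slc12a2, a chloride importer, was below the exporter Slc12a5 with -2.90 ± 1.09, and Gad2 was below Gad1 with -3.17 ± 2.62. Pdgfra over Mbp was 0.12 in pup 1 and -1.09 in pup 3 and was not given a direction. Where the second gene was at 0, the size of the ratio depended on the pseudocount of 1.

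**Figure D2:**
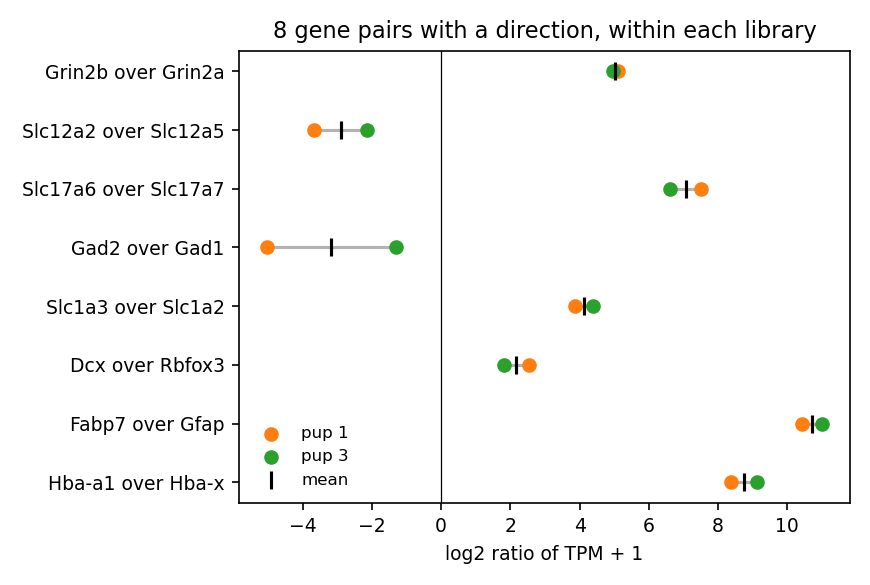
Log2 ratio of TPM + 1 for the 8 gene pairs given a direction, within the library of pup 1 and of pup 3, with their mean as a black tick. Each pair kept 1 side of 0 in both pups, from -3.17 ± 2.62 for Gad2 over Gad1 to 10.72 ± 0.40 for Fabp7 over Gfap.

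The comparison of pups asked how far 2 libraries of this input held the same genes. In pup 1 10166 genes were detected and in pup 3 9367, of which 7389 were shared, 60.8% of the 12144 genes seen in either. Of the shared genes, 6836 were protein coding and 51 were lincRNA genes. No ERCC spike-in of pup 1 lay from 1 to 15 TPM, so how many RNA molecules a level in this range stands for is unknown. At TPM 10 the shared genes were 5356. A further 2777 genes were seen in pup 1 only and 1978 in pup 3 only. Across genes, log2(TPM + 1) had Pearson r = 0.465 and Spearman rho = 0.490. Over the 1667 genes with a mean TPM of 100 or more, a limit chosen after seeing the data, r was 0.701. At a mean TPM of 10 or more it was 0.317. Genes read at 1 to 5 TPM in pup 1 had under 3 counts in pup 3 in 38.5% of 1461 cases, against 23.4% of 2793 at 20 to 50, 10.8% of 1572 at 50 to 100 and 2.75% of 1162 at 100 to 300. From pup 3 to pup 1 the shares were 29.2% of 1195, 18.5% of 2696, 7.03% of 1564 and 1.95% of 1182. By mean TPM, a class that a miss in 1 library itself lowers, the median fold difference of TPM + 1 was 4.59 at 1 to 5 TPM, 12.4 at 5 to 10, 16.6 at 10 to 20, 2.42 at 20 to 50, 1.87 at 50 to 100, 1.58 at 100 to 300 and 1.39 at 300 or more. The added 1 holds down folds at low levels. In these classes, 63.4% of genes at 1 to 5 TPM and 42.9% at 10 to 20 had under 3 counts in at least 1 library.

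**Figure D3:**
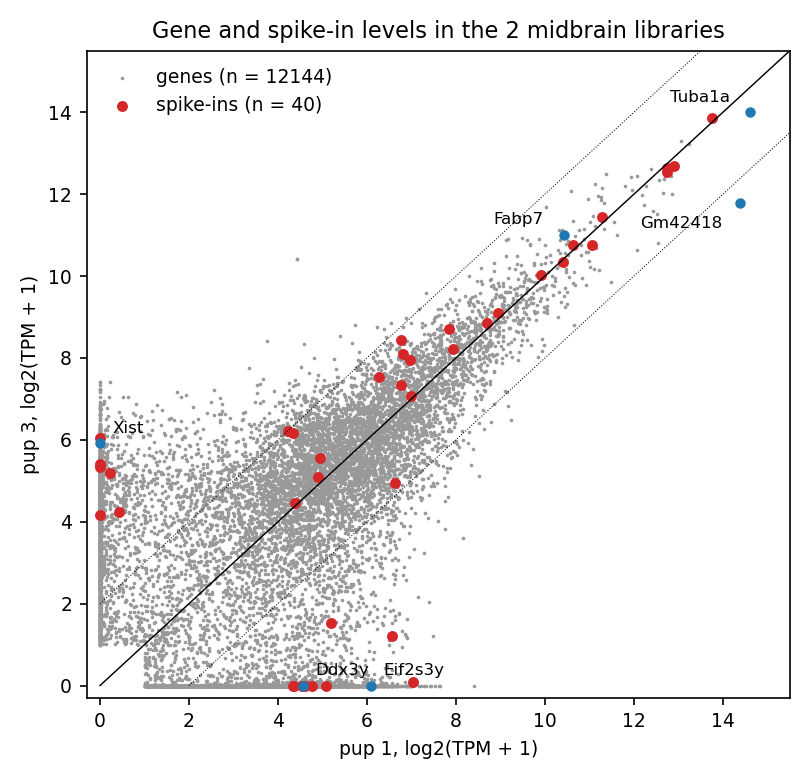
Levels of 12144 genes (grey) and 40 spike-ins (red) in pup 1 against pup 3 as log2(TPM + 1), with the line of equal values, dotted lines 2 log2 units (4-fold) apart from it and named genes in blue. Many genes lie on an axis, at or near 0 in 1 library, and r across genes was 0.465.

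By the size rule, 5982 genes differed over 4-fold between the libraries, 3374 higher in pup 1 and 2608 higher in pup 3. In 4016 of them the lower library had under 3 counts, and 67 of the 5982 had a mean TPM of 100 or more. Those with the largest ratio at a mean TPM of 20 or more were near 0 in the other library. Higher in pup 1 was Rtcb (ENSMUSG00000001783.3, chromosome 10, 85938637 to 85957823), an RNA ligase, with 10477 counts and 0, at least 3535-fold. Then came Vps16 with at least 2094-fold, Sgcb with at least 2012-fold, Zmiz2 with at least 1949-fold and Nadk with at least 1929-fold. Higher in pup 3 were Xist with 0 and 23927 counts, at least 5211-fold, Mmp16 with at least 1531-fold and Gpc6 with at least 1160-fold. Crbn (2.16 and 5461 counts, ratio interval 607 to 18118) and Spg11 (1.03 and 5397 counts, interval 778 to 171291) had 1 to 3 counts in pup 1. The rule lists reads of 2 libraries, and which of these genes differ between pups was not tested.

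Of 27 lists given a percentile, 18 had a median ratio below 0, that is higher in pup 1. Percentiles were under 5 for 5 lists and over 95 for 0, and whether the lists share a lean was not tested. Of the 27, 1 lay outside the middle 95% of random lists, against 1.35 expected by chance. This was the heat shock list, with a median log2 ratio of pup 3 over pup 1 of -0.89 at percentile 2.35, and its members went both ways. It lay inside the range under each of 4 alternatives. The median ratio was -0.37 for pan-neuronal genes (percentile 4.09), -0.28 for ribosomal proteins (2.74), -1.59 for glutamatergic and tectal genes (3.48), -3.90 for sex-linked genes (4.04), -0.37 for housekeeping genes (6.22) and 0.89 for axon guidance genes (90.5).

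Sex-linked genes were split between the pups. Xist, the noncoding RNA that silences an X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), read 0 TPM in pup 1 and 59.5 in pup 3, and its antisense gene Tsix 0 and 8.41, which cannot be told from Xist where counting ignores strand. The Y-linked genes Eif2s3y (67.4 and 0), Ddx3y (22.6 and 0) and Kdm5d (14.99 and 0.07, with 855 and 9 counts) were read in pup 1. Uty, Usp9y and Zfy1 were at 0 in both. Xist and these 3 Y-linked genes each differed over 4-fold.

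Transcript choice agreed in part. Of 5311 genes with at least 2 transcripts and 50 counts in each library, 3337 had the same most abundant transcript in both pups, 62.8% (exact 95% interval 61.5% to 64.1%), and the share of pup 1's leading transcript differed by a median of 19.3 percentage points. Among 1247 of these genes at a mean TPM of 100 or more the agreement was 82.0%. Snap25, a synaptic fusion protein, kept ENSMUST00000028727.6 at 80.3% ± 1.68 of its abundance and Ncam1 kept ENSMUST00000193547.1 at 73.5% ± 5.29. Cdc42 kept ENSMUST00000030417.9 at 65.5% ± 14.6 and Gria2 kept ENSMUST00000107745.3 at 66.9% ± 8.52. Mapt changed its leading transcript, from ENSMUST00000106992.5 (42.2% in pup 1, 36.2% in pup 3) to ENSMUST00000106993.5 (33.0% and 41.5%). For Clta, ENSMUST00000107849.5 held 80.6% in pup 1 and 27.1% in pup 3, and ENSMUST00000107851.5 held 0% and 51.5%. Map2 led with ENSMUST00000024639.7 in pup 1 (39.5% and 22.4%) and ENSMUST00000156636.4 in pup 3 (11.9% and 27.4%). Dnm1l led with ENSMUST00000023477.9 (50.6% and 36.5%) and ENSMUST00000096229.5 (28.4% and 37.4%). Leaders were set by TPM, where short transcripts weigh more than in counts. In pup 3 ENSMUST00000156636.4, of length 546, had 889 counts against 8283 for ENSMUST00000024639.7. For Mapt, ENSMUST00000106993.5 had 12572 counts there against 39509 for ENSMUST00000106992.5. By counts Cdc42 led in pup 1 with ENSMUST00000051477.8 (14150 against 11692). Some kept or changed leaders thus depend on the measure.

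Spike-in RNAs took 2.05% of counts in pup 1 (exact 95% interval 2.05% to 2.06%) and 2.21% in pup 3 (2.21% to 2.22%), a mean of 2.13% ± 0.113. Of 96 ERCC spike-ins, 34 had at least 3 counts in pup 1 and 33 in pup 3, 27 of them in both. Across the 40 seen in either library, r of log2(TPM + 1) was 0.684 and rho 0.769. Mitochondrial genes took 2.79% and 2.66% of counts, or 4.01% and 3.87% with 5 nuclear pseudogenes added. Haemoglobin genes took 0.0518% (0.0509% to 0.0527%) in pup 1 and 0.0966% (0.0956% to 0.0977%) in pup 3, and ribosomal protein genes 1.96% and 1.68%. The intervals of these shares cover counting error only, not amplification from few molecules, so they do not test a difference between pups. The 10 genes with the most counts held 9.45% and 6.31% of counts and the top 100 held 25.1% and 21.6%, and Gm42418 alone held 2.27% and 0.417%.

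**Figure D4:**
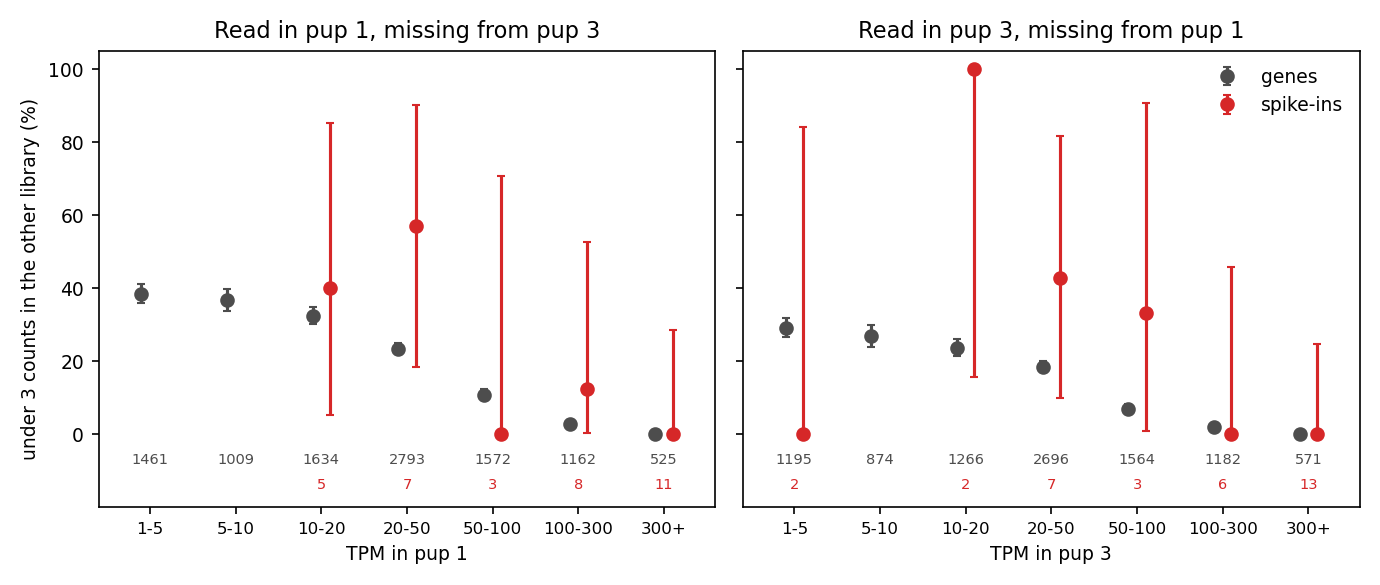
Percent of genes (grey) and spike-ins (red) read in pup 1 with under 3 counts in pup 3 (left), and read in pup 3 with under 3 in pup 1 (right), by the level in the library that holds them, with exact 95% intervals and the numbers below. For genes the share went from 38.5% to 0.190% and from 29.2% to 0%, and 1 of 8 spike-ins at 100 to 300 TPM in pup 1 was missing from pup 3.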

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

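The tRNA part of the tables was not used in any comparison. In pup 3 it held 4 expected counts, all in 1 of 26248 rows, above the 3 counts that a count of 0 allows, and in pup 1 it held 0. No explanation for these counts was tested.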

How the results depend on the processing

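The correlation across genes moved from 0.465 to 0.271 with a pseudocount of 0.1, 0.690 with a pseudocount of 10, 0.796 with no filter, which adds genes at 0 in both libraries, 0.317 at a mean TPM of 10 or more and 0.486 with FPKM. At a mean TPM of 100 or more, an alternative chosen after seeing the data, it was 0.701. Without mitochondrial genes and spike-ins, with TPM rescaled, it was 0.456. The number of lists outside the middle 95% went from 1 to 0 with a pseudocount of 0.1, with TMM scaling and with members detected in both libraries, where only 16 of the 27 lists had a percentile. With 10 bins it stayed at 1 but the list was the sex-linked one (percentile 2.07). The heat shock percentile ranged from 2.58 to 15.2. Isoform agreement was 64.6% at 200 counts. In TPM, where short RNAs weigh more, spike-ins held a mean of 4.60% and the top 100 genes 29.4%. Haemoglobin genes went from a mean of 0.0742% of counts to 0.228% of TPM. Ribosomal protein genes went from 1.82% to 4.72% and mitochondrial genes from 2.72% to 5.26%. The cause of the other shifts was not tested.

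Shared genes numbered 5356 to 10936 over 4 alternatives, the highest with posterior mean TPM. That number exceeds the 8621 shared at a TPM of 0.1, so it includes genes under this TPM in at least 1 library. Of 35 lists, 18 had a count of members in both pups that moved by over 1.5 times under an alternative, 13 of them with another detection rule. At TPM 10 the count fell from 11 to 4 for axon guidance, 3 to 1 for dopaminergic, 5 to 3 for GABAergic, 4 to 2 for forebrain, 4 to 2 for oligodendrocyte precursor and 3 to 1 for cell cycle genes, and to 0 for the cholinergic, neurogenic, immediate early and other organ lists. At TPM 0.1 it was 5 for cell cycle and 2 for cerebellar genes. Leaving out each library, the genes detected in the other were 9367 to 10166, list members detected 244 to 247 against 209 in both, pairs with a direction 9 to 10, the spike-in share 2.05% to 2.21% and the top 100 share 21.6% to 25.1%. The correlation and the 4-fold count need both libraries. The 4-fold count was 4914 with 8-fold, 8064 with 2-fold and between 5122 and 5969 otherwise, including scaling by spike-ins, chosen after seeing the data (5963). The share higher in pup 3 stayed between 41.4% and 47.1%. Among listed genes at a mean TPM of 20 or more, 671 were higher in pup 1 and 671 in pup 3. All 14 named genes tested kept their call and direction. They were the genes with the largest ratios and sex-linked genes, so this does not bear on the other listed genes. Depth stays open as a limit for genes under a mean TPM of 1, where those missing from 1 library had a median of 12 counts in the other.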

Other observations

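Other gene groups were looked at after the data were seen, with no test against the remaining genes. All 12 tubulins measured were detected in both pups, among them Tubb5 (1959 ± 439 TPM, SD, n = 2), Tubb2b (1882 ± 1358) and Tuba1b (1694 ± 474), with Tuba1c lowest (2.01 ± 0.396). All 11 cell adhesion genes were in both, with Cdh13 at 188 ± 30.3, L1cam at 127 ± 13.3, Cntn1 at 124 ± 13.6 and Chl1 at 109 ± 1.99. Of 8 high mobility group proteins, which bind chromatin, 7 were in both, led by Hmgn2 (837 ± 136) and Hmgb1 (647 ± 264).

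Of 17 imprinted genes, which are read from 1 parental copy, 12 were in both pups, with Nnat at 4083 ± 991, Ndn at 1667 ± 279, Meg3 at 1464 ± 2.92, Snrpn at 1350 ± 363 and Peg3 at 66.7 ± 1.12, while Dlk1 was at 2.46 ± 1.79. H19 read 53.2 in pup 1 and 0.19 in pup 3, and Plagl1 0 and 37.6. The calmodulin gene Calm2 (3071 ± 899) and the calcium binding proteins Calb2 (204 ± 48.8) and Calb1 (46.8 ± 21.3) were in both, and Pvalb was at 0.

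Of the tests that follow, those of genes missing from 1 library and of the sex-linked genes were chosen only after the result was seen, while those on length, GC content and shared reads were set before. Classes set by the level in 1 library were also added afterwards. In all, 4937 genes had 3 or more counts in 1 library and under 3 in the other. Their median count in the library that held them was 296, and 64.3% had 100 or more, which argues against too few reads as the main source, although the 1450 of them under a mean TPM of 1 had a median of 12 and there it stays open. A first form of this test, over genes with a mean TPM of 5 or more, gave a median of 928, but that limit itself favours high counts. Spike-ins, added to the RNA rather than made by the pups, were missing as well. Of 12 at 5 to 50 TPM in pup 1, 6 had under 3 counts in pup 3 (exact 95% interval 2.53 to 9.47), where genes of the same level in pup 1 give 3.26. Of 9 at 5 to 50 TPM in pup 3, 5 were missing from pup 1 (1.91 to 7.77), where genes give 1.77. That spike-ins were missing at least as often as genes goes with chance sampling of few RNA molecules at the levels these spike-ins cover. The lowest of them stood at 17.8 TPM in pup 1 and 17.06 in pup 3. They do not bear on genes at lower levels, and of the 4937 genes 1450 were under a mean TPM of 1 and 1169 at 1 to 5. A difference between the pups as the main source stays open, since the spike-ins are few and the first interval holds the gene value. A first form of this test sorted spike-ins by mean TPM (12 of 19 missing against 6.45) and is not relied on, because a low mean goes with a miss by construction.

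Among abundant genes the spread between libraries was compared with that of spike-ins, and the outcome depended on how abundance was set. By mean TPM of 100 or more, the SD of the log2 ratio of pup 3 over pup 1 was 0.917 over 1667 genes, weighted to the abundance of the spike-ins, against 0.576 over 19 spike-ins (bootstrap 95% interval 0.353 to 0.709). By a TPM of 100 or more in pup 3 it was 1.31 for 1753 genes and 0.576 for 19 spike-ins. By a TPM of 100 or more in pup 1 it was 1.40 for 1687 genes and 1.75 for 19 spike-ins (interval 0.366 to 2.82), where ERCC-00022, at 129.9 and 0.07 TPM, is included; its mean of 65.0 hides it from the first comparison. A wider spread of genes was thus not shown. With mean TPM, the SD of genes was 0.881 after removing a trend on length, 0.914 after one on GC content and 0.912 over the 1527 genes whose counts were fixed to within 1%. The length trend took up 6.67% of the variance of these genes' log2 ratio, and the GC trend 0.286%. These values argue against either trend as the main source of the spread of these genes. The SD over genes with fixed counts, 0.912 against 0.917, argues the same for shared reads. The bound set for these tests was the first spike-in interval, which does not hold for pup 1. Whether length, GC content or shared reads set genes apart from spike-ins therefore stays open. A difference between the pups in gene expression could not be separated from the library, with 1 library per pup.

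The sex-linked genes divide the pups, and the hypothesis is that pup 1 may be male and pup 3 female, which the labels do not state. Xist and the 6 Y-linked genes of the list were compared with random sets matched on mean TPM; Tsix was left out because it overlaps Xist. In 0.7% of 10000 draws the gene in the place of Xist and 3 or more of the others differed over 4-fold in opposite directions, with none in the same, which argues against chance sampling. A first form of this test took Xist and the 3 Y-linked genes read, and over these draws it gave the same 0.7%, as genes drawn for those at 0 added no call. Xist in pup 1, its 0 counts taken as 3, was 0.0125% of its count in pup 3. That 0 is part of the division itself, so it is no separate test of carry-over of reads from pup 3 into pup 1. Kdm5d in pup 3 was 1.05% of its count in pup 1 (lower 95% bound 0.482%). Carry-over at that lower bound would leave at most 4.89 of the 5114 genes with 1000 or more counts in pup 1 at 0 in pup 3, and 517 were at 0 (exact 95% interval 475 to 561). This argues against carry-over from pup 1 into pup 3 as the origin of the Kdm5d counts, and carry-over would blur such a division rather than make it. The design holds no record of sex, so this biological explanation was not tested.

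In pup 1 no spike-in lay from 1 to 15 TPM and 12 lay from 15 to 50, while 3350 genes lay in the lower range and 3557 in the upper. In pup 3 the lower range held 2 spike-ins and 2743 genes. The amount of each spike-in added was not used here, so the number of molecules behind a level of 1 to 15 TPM is unknown. Rn7s1, a signal recognition particle RNA, read 20.4 TPM in pup 1 and 1374 in pup 3, and the related Rn7s2 had the same values. The deposited posterior SD of Rn7s1 was 37.2 of 67 counts in pup 1 and 2796 of 6289 in pup 3, so the level of each gene is uncertain. The deposited TPM intervals of the libraries still lay apart. For Rn7s1 the upper bound in pup 1 was 39.2 and the lower bound in pup 3 634, and for Rn7s2 37.1 and 236.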
